A study of Mus musculus with 10 samples.

How the data were processed

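Poly(A) RNA of mouse primary lymphatic endothelial cells was captured with oligo(dT) beads, fragmented, primed with random hexamers and sequenced from circular single-stranded DNA libraries, per the labels' protocols. The deposited table holds 1 estimated count per gene and library for 16251 genes, with an Entrez gene ID and a symbol, and it was made by the authors before deposit. Values are not normalized, and between 10.5% and 11.3% of the genes in a library have a fractional value, a feature of RSEM's estimated counts where reads match several genes. HISAT2 2.2.1, Bowtie2 2.4.5, RSEM 1.3.1 and the build GRCm38.p6 are named in the submitters' processing notes. Their roles, the gene annotation, the strand setting and any gene filter are not given in the sources used here. Of the gene IDs, 16202 matched the reference gene table of that build, from which coordinates were taken.

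Groups came from the labels of the 10 samples (5 control, 5 Vegfr2 siRNA), and columns were matched to samples by name. The label protocols describe transfection for the study as a whole and do not name a control siRNA. Totals ran from 17946483 to 18239260 estimated counts, and the 10 most abundant genes took 3.85% to 3.94% of them in control and 3.22% to 3.32% in siRNA libraries. In pairs of libraries of a group, counts differed by more than sampling noise (chi-square per degree of freedom from 1.50 to 3.47 over genes with at least 20 counts in the pair), so no library was counted as a repeat of another.

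Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr with a minimum count of 10, a robust quasi-likelihood fit with group as the only term, the quasi-likelihood F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 12161 genes, with 4090 under the filter. Adjusted p-values of single genes in the text are from this fit. CPM values use TMM-scaled library sizes. A rise or fall is stated only for genes past the threshold. For Kdr an exact permutation test over all assignments of the libraries was added. The glmTreat test asked for a fold of more than 1.5.

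Before the data were examined, 28 gene lists were written, and the 25 with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation of 0.01) and adjusted over the lists. Kdr was in no list. With a correlation estimated from the data, 0 of the 9 called lists passed (lowest adjusted p = 0.0651), and with fry 20 lists did. The genes named in the text also follow a rule set before the data were examined. It takes Kdr, the 15 genes with the largest rise and the 15 with the largest fall among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups, leaving out unnamed loci and pseudogenes. To these it adds up to 4 members of each list with the smallest adjusted p and 21 fixed names. Together these are 143 tested genes, and any other gene is said to be chosen after its values were seen or is named only as a list member or a carrier of the word below.

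GENCODE M21 (GRCm38) gave transcript length, GC content, exon positions and the longest annotated 3' UTR of each gene. Genes with exon bases shared with another annotated gene over more than 10% of their length among those named are Mt2, Fosl1, Nefl, Ctsd, Ccn2, Fdft1, Icam1, Gadd45a, Nefm, Egfl7, Tgfb3, Ifi47 and Ccne2. Reads of Fosl1, Tubb2b, Loxl2, Fdft1, Ccne2 and Rps6 were divided between genes in all 10 libraries. Matches to a seed of the siRNA were searched as 7-base words in 3' UTRs of at least 50 bases (11821 of 12160 tested genes other than Kdr, 97.2%). For each of 15915 words present in at least 100 genes, the log2 fold change was regressed on presence of the word with terms for UTR length, UTR GC content and expression level, with Bonferroni adjustment, in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1.

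The methods were tested on simulated data for the comparison of siRNA with control. With 200 of 12161 genes changed, the edgeR test recovered 40% of genes changed by 1.1-fold, 84% at 1.25-fold, 84% at 1.5-fold and 96% at 2-fold, with 5 false calls (3.18% of calls). The real comparison called 8668 genes, so these rates were not tested where most genes change. Camera called 1 list when 1 was raised by 1.3-fold. In the word search over 11821 genes, a planted lowering of 0.15 log2 put the planted word at rank 1, and 0 words passed with nothing planted. Fold changes were permuted over genes there, whereas in the unpermuted data 6 words tied to higher fold changes passed. Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 5 CPM, the replicate number as a block, glmTreat, each library left out, an estimated correlation, and fry. Removal of GC content and length trends, and leaving out genes with the 3' UTR word, were added after seeing the data.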

Results

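Messenger RNA was measured by sequencing in 10 libraries of mouse primary lymphatic endothelial cells (LECs), the cells that line lymphatic vessels. In 5 libraries, labelled Vegfr2 siRNA, the cells had received 50 nM of small interfering RNA against Vegfr2, a short duplex that directs the cell's silencing machinery to a matching transcript, and the other 5 libraries were labelled control. RNA was taken after 48 h. Vegfr2 is the receptor for vascular endothelial growth factor (VEGF) encoded by the gene Kdr. The libraries held 17946483 to 18239260 estimated reads on genes. The control samples carry the same treatment tag, siRNA knockdown, as the others, but the labels do not say whether they were transfected with another siRNA, nor whether replicates were separate cultures. The p-values therefore measure the spread between these samples, which may be technical. By its title, the series asks whether loss of endothelial VEGFR2 moves lymphatic cells toward a hematopoietic (blood cell) transcriptional program.

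The target transcript was strongly reduced. Kdr (Entrez gene 16542, GRCm38.p6 chromosome 5, 75932827 to 75979072) stood at 1323 ± 66.3 CPM (counts scaled to a common library size) in control cells and 186 ± 14.8 CPM after siRNA (SD, n = 5 each), which is 14.0% ± 1.12 of the control level. In the 5 control libraries, in the order of their labels, Kdr was at 1328, 1320, 1280, 1259 and 1431 CPM. In the 5 siRNA libraries it was at 191, 196, 200, 173 and 167 CPM. The log2 fold change was −2.83 (SE 0.059, adjusted p = 3.14e-11). A two-sided exact permutation test on log2 CPM gave p = 0.00794, the smallest that the possible assignments of the libraries allow.

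**Figure D1:**
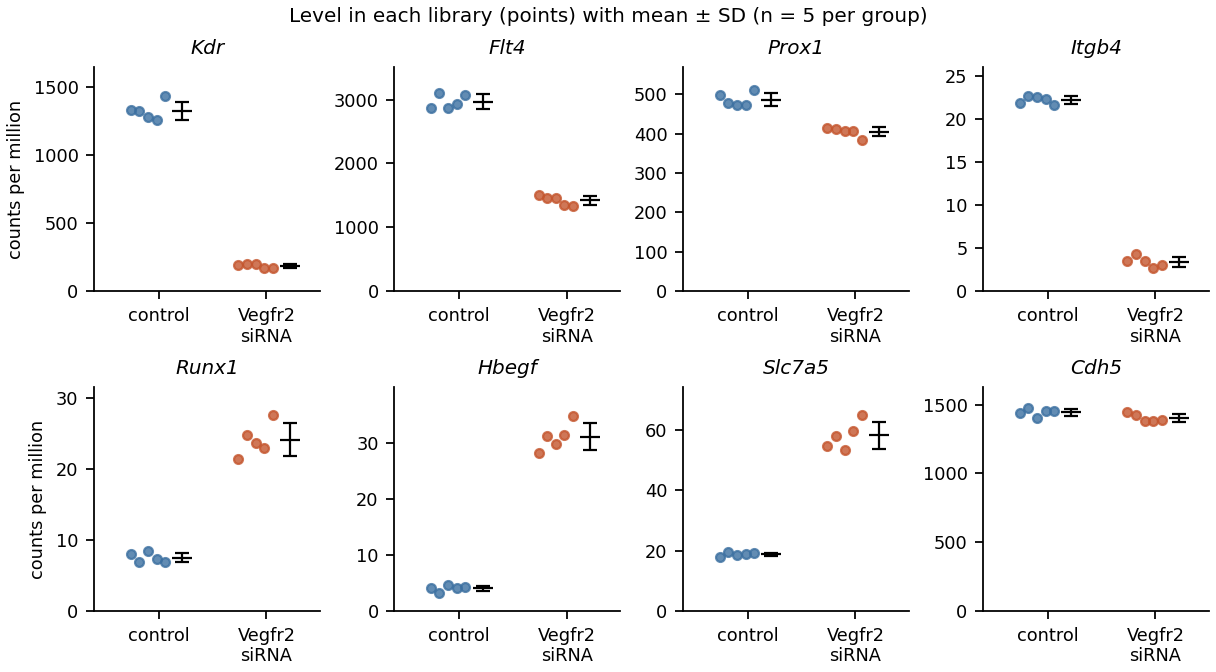
CPM (vertical axes, from 0) of 8 genes in each library (points) of the control and Vegfr2 siRNA groups, with the mean and SD of each group (bars, n = 5). Kdr fell from 1323 to 186 CPM, Flt4, Prox1 and Itgb4 were also lower, Runx1, Hbegf and Slc7a5 were higher, and Cdh5 did not pass the test.

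The transcriptome of the siRNA cells differed broadly from that of control cells, mostly by small amounts. Of 12161 genes tested, 8668 changed (71.3%), 4391 upward and 4277 downward, and the median size of their change was 1.23-fold. Of these genes 561 reached at least 2-fold, of which 235 were higher and 326 lower. Tested against a fold of 1.5 instead of any change, 1041 genes passed, 447 higher and 594 lower. The 2 groups' libraries did not overlap for 6931 tested genes (57.0%), where chance gives 0.794%. Libraries of a group were close to each other, with a biological coefficient of variation of 2.85%.

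**Figure D2:**
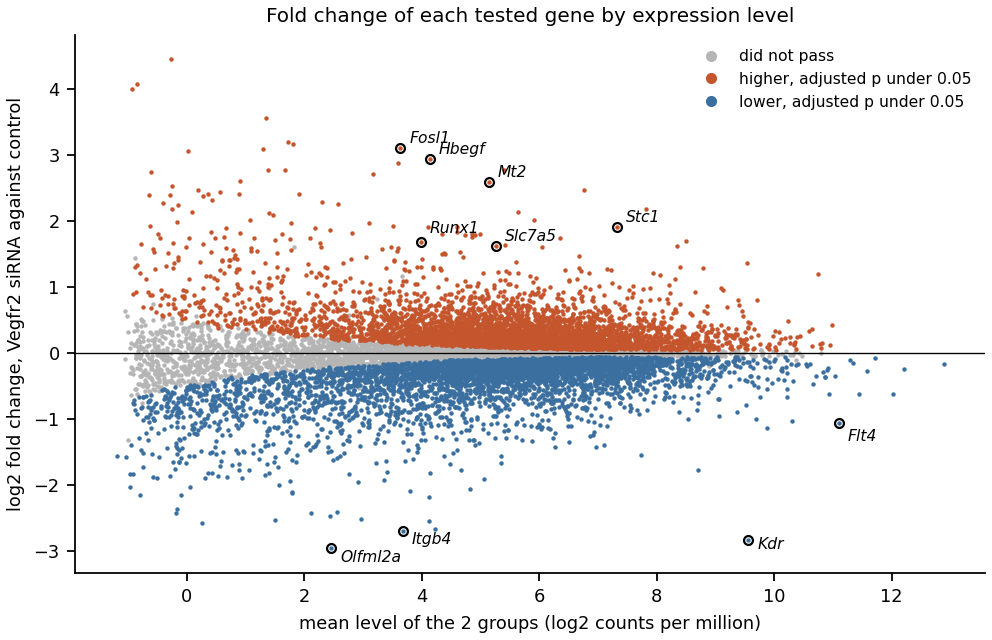
Log2 fold change (vertical axis, Vegfr2 siRNA against control) of the 12161 tested genes by their mean level (horizontal axis, log2 CPM, logarithmic), with higher genes in orange, lower genes in blue and genes that did not pass in grey. Kdr (−2.83) lies far below other genes of its level, and 4391 genes were higher and 4277 lower.

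Among genes of at least 5 CPM on average, Fosl1 and Hbegf had the largest rises. Fosl1, a subunit of the AP-1 transcription factor (Entrez gene 14283, chromosome 19, 5447698 to 5455938), rose from 2.57 ± 0.526 to 22.3 ± 1.59 CPM (SD, n = 5), a log2 fold change of 3.11 (SE 0.090, adjusted p = 6.06e-30). Hbegf, a ligand of the EGF receptor (Entrez gene 15200, chromosome 18, 36504927 to 36515805), rose from 4.04 ± 0.488 to 31.1 ± 2.41 CPM, and Sema7a, a membrane semaphorin, from 81.4 ± 3.26 to 371 ± 19.6 CPM (SD, n = 5). The neurofilament genes Nefm and Nefl rose by 2.77 and 2.14 on the log2 scale, and the tubulin gene Tubb2b by 1.92. The rest of the 15 were Slc9a2, Kcnh1, Mt2, Nptx1, Emilin3, Sh2d5, Ctxn1, Clec4d and Stc1, with log2 fold changes from 1.92 for Stc1, a secreted glycoprotein, to 2.88 for the sodium/proton exchanger gene Slc9a2. Reads of Fosl1 and Tubb2b were divided between genes in all 10 libraries. Exons of Mt2 (73.5%), Fosl1 (62.4%), Nefl (32.8%) and Nefm (19.2%) share bases with a gene on the opposite strand, and since no strand setting is stated, their levels are uncertain to that extent. Nefl and Nefm share these bases with each other, so their rises may not be independent.

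The largest falls by the same rule were those of Olfml2a, Kdr and Itgb4. Olfml2a, an olfactomedin-like extracellular protein (Entrez gene 241327, chromosome 2, 38931980 to 38960585), fell from 9.76 ± 0.601 to 1.251 ± 0.165 CPM (SD, n = 5), a log2 fold change of −2.96 (SE 0.115, adjusted p = 1.65e-25). Itgb4, the integrin beta 4 subunit that binds laminin (Entrez gene 192897, chromosome 11, 115974725 to 116008412), fell from 22.2 ± 0.454 to 3.45 ± 0.580 CPM (SD, n = 5). The potassium channel gene Kcnn3 fell by 2.67 on the log2 scale and Lrg1, a secreted glycoprotein of the endothelium, by 2.05. The other genes were Btnl9, Slc18a1, Ip6k3, Serpina3i, Thrsp, Cyp1a1, Rcan2, Aldoc, Pglyrp1 and Scn3b, with log2 fold changes from −2.54 for Btnl9 to −1.83 for Scn3b. Reads of Serpina3i were divided between genes in 6 libraries.

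Genes of lymphatic endothelial identity were lower as a group. Of 20 tested members, 18 fell and 2 rose, with the same counts adjusted over the list alone, and the median log2 fold change was −0.56 (camera adjusted p = 5.71e-10; adjusted p = 0.129 with an estimated correlation). Flt4, which encodes the VEGF-C receptor VEGFR3 (Entrez gene 14257, chromosome 11, 49609679 to 49652739), fell from 2967 ± 114 to 1424 ± 71.4 CPM (SD, n = 5). The VEGF co-receptor gene Nrp2 fell from 861 ± 43.4 to 464 ± 18.7 CPM, the integrin gene Itga9 by 1.07 and the scavenger receptor gene Stab2 by 1.64 on the log2 scale. Prox1, the transcription factor that specifies lymphatic fate (Entrez gene 19130, chromosome 1, 190118035 to 190170827), fell from 487 ± 17.1 to 405 ± 12.2 CPM, a log2 fold change of −0.26 (adjusted p = 2.29e-12). The hyaluronan receptor gene Lyve1 (−0.24) and the transcription factor genes Nr2f2 (−0.24), Sox18 (−0.46) and Maf (−0.60) also fell. Pdpn, which encodes the lymphatic surface protein podoplanin, rose from 11.2 ± 1.54 to 19.5 ± 1.79 CPM. Flt4, Prox1, Maf and Reln carry the 7-base word GTAAAGA, described in the final paragraph, in their 3' UTRs, and without these 4 genes 14 of 16 members fell and the median was −0.48 (camera adjusted p = 1.85e-08; adjusted p = 0.0887 with an estimated correlation).

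Pan-endothelial genes were also lower. Of 29 tested members, 23 fell, 4 rose and 2 did not pass, and the counts were equal adjusted over the list alone (median log2 fold change −0.32, camera adjusted p = 4.43e-09; adjusted p = 0.0651 with an estimated correlation). The adhesion gene Icam2 fell by 0.70 on the log2 scale, the angiopoietin receptor relative Tie1 by 0.66, the guidance receptor gene Robo4 by 0.58 and Egfl7, whose exons share bases with another gene, by 0.52. Pecam1 fell by 0.21, while Cdh5, which encodes VE-cadherin, stood at 1444 ± 25.9 CPM in control and 1403 ± 29.4 CPM in siRNA cells (SD, n = 5; adjusted p = 0.0991). Tie1, Tal1, Ptprb and Nos3 carry the 7-base word, and the call stayed without them (camera adjusted p = 2.69e-09; adjusted p = 0.0423 with an estimated correlation). Among VEGF ligands and receptors other than the target, 3 of 8 tested members fell, 1 rose and 4 did not pass, equally adjusted over the list alone (camera adjusted p = 0.0229; adjusted p = 0.265 with an estimated correlation). Those that fell were Flt4, Nrp2 and Nrp1 (−0.81), and Vegfa rose by 0.91 from a low level of 2.91 CPM. Vegfc, the main lymphatic growth factor gene, was under the filter, with 34 counts over the control and 21 over the siRNA libraries. Flt1, the VEGFR1 gene, had a log2 fold change of −0.02 (adjusted p = 0.598), which ran from −0.0323 to 0.0198 under other settings. This list's call was lost without a filter on low counts (adjusted p = 0.0607) and without Flt4 and Flt1, its 2 carriers of the word (adjusted p = 0.169).

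Hematopoietic transcription factors and progenitor genes moved in both directions. Runx1, a master regulator of definitive blood cell emergence (Entrez gene 12394, chromosome 16, 92601466 to 92826074), rose from 7.54 ± 0.673 to 24.2 ± 2.32 CPM (SD, n = 5), a log2 fold change of 1.68 (SE 0.071, adjusted p = 1.57e-23). The adhesion receptor gene Cd44 rose by 1.08 on the log2 scale, Kit, the stem cell factor receptor gene, by 0.53, Gata2 by 0.16 and Tal1 by 0.13. Lyl1 fell by 0.94, the corepressor gene Cbfa2t3 by 0.68 and Lmo2 by 0.25, and Cd34 had a log2 fold change of 0.06 (adjusted p = 0.371; from 0.0208 to 0.0965 under other settings). Over the whole list, 9 of 22 tested members rose, 7 fell and 6 did not pass, and 9 rose and 8 fell adjusted over the list alone. The list was not called (median log2 fold change 0.05, camera adjusted p = 0.741), although fry, which asks only whether its genes move on balance one way, gave an adjusted p of 0.00514. The median ran from 0.027 to 0.071 when a library was left out and was 0.14 at a mean of at least 5 CPM. Spi1 and Gfi1, transcription factor genes of myeloid and other blood cells, were under the filter. They had at most 1 and 2 counts in any library. Ptprc, Gata1, Gfi1b, Ikzf3, Bcl11a and Cd48 of this list had no entry under these symbols among the deposited genes. Tal1, Mecom and Meis1 carry the 7-base word.

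Tested markers of myeloid cells were lower after the siRNA. All 6 of them fell, also adjusted over the list alone (median −0.60, camera adjusted p = 0.0229; adjusted p = 0.179 with an estimated correlation), among them the mannose receptor gene Mrc1, which lymphatic endothelium also expresses, from 72.5 ± 4.44 to 34.0 ± 2.95 CPM, and Cd14 from 92.3 ± 6.43 to 65.8 ± 2.32 CPM (SD, n = 5), while 15 members were under the filter. That call was lost without siRNA replicate 2 (adjusted p = 0.0503) and without a filter on low counts (adjusted p = 0.123). Of the genes written for these lists, 21 of 32 myeloid, 9 of 18 lymphoid and 8 of 18 erythroid and megakaryocytic genes had deposited values. Adgre1, Lyz2, Cd3e and the globin genes were among those without. The tested genes therefore cover a small part of each list. Of lymphoid genes, Cd27 fell by 1.86 from 1.29 CPM and Lck had a log2 fold change of −0.13 (adjusted p = 0.173; −0.0786 without siRNA replicate 3), with 7 members under the filter. Of erythroid and megakaryocytic genes, the transferrin receptor gene Tfrc rose from 48.7 ± 2.22 to 97.2 ± 5.90 CPM (SD, n = 5) and Pf4 fell by 0.88. Of the 7 tested fibroblast and mural cell genes, Acta2 rose by 0.62, Pdgfrb (−0.41) and Notch3 (−0.57) fell and 4 did not pass, with equal counts adjusted over the list alone. Pdgfra of that list, singled out after its values were seen, was under the filter, with 5 counts over the control and 45 over the siRNA libraries. The epithelial list had 1 tested member, the keratin gene Krt18, which rose from 1.67 ± 0.469 to 8.22 ± 0.383 CPM (SD, n = 5).

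Genes of the growth factor and VEGF response were higher after the siRNA. Of 32 tested members, 19 rose, 10 fell and 3 did not pass, with equal counts adjusted over the list alone (median log2 fold change 0.43, camera adjusted p = 2.36e-06; adjusted p = 0.0651 with an estimated correlation). The immediate early gene Egr1 rose from 54.1 ± 1.68 to 150.0 ± 6.40 CPM (SD, n = 5), Stc1 from 66.8 ± 3.93 to 253 ± 7.76 CPM, and the signalling inhibitor gene Spry4 by 0.69 on the log2 scale. Of members singled out after their values were seen, Egr2 (2.44) and Egr3 (2.14) rose, and Spry1 (−0.97), Nr4a2 (−0.57), Esm1 (−0.53) and Rcan1 (−0.49) fell. Egr2 and Egr3 are not among the 15 largest rises, so they missed that rule's mean of 5 CPM or its lack of overlap. Of the members 5 carry the 7-base word, Spry1 and Nr4a2 among them, and the call stayed without them (camera adjusted p = 4.38e-09; adjusted p = 0.0423 with an estimated correlation). The word was picked for its tie to lower fold changes in these data, so leaving carriers out favours an upward list. That call is therefore no independent check.

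Genes of the integrated stress and unfolded protein response were also higher. Of 25 tested members, 22 rose, 2 fell and 1 did not pass (22 and 3 adjusted over the list alone), with a median log2 fold change of 0.46 (camera adjusted p = 4.01e-08; adjusted p = 0.0651 with an estimated correlation). The amino acid transporter genes Slc7a5 and Slc3a2, whose products form one heterodimer, rose by 1.63 and 0.56, and Shmt2, an enzyme of mitochondrial one-carbon metabolism, by 0.81. Atf4 (0.91), Chac1 (1.74), Slc7a11 (1.62) and the chaperone genes Hspa5 (0.46) and Hsp90b1 (0.14), chosen after their values were seen, also rose. Ddit4, an inhibitor of mTORC1, fell by 1.03. Glycolysis and hypoxia genes were also higher, with 15 of 24 members up, 5 down and 4 that did not pass, equally adjusted over the list alone (median 0.10, camera adjusted p = 0.0171; adjusted p = 0.404 with an estimated correlation). Hk2, a hexokinase gene, rose by 1.59, the vasodilator peptide gene Adm by 1.22 and the glucose transporter gene Slc2a1 by 0.62.

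Basement membrane and matrix genes, and genes of cholesterol and fatty acid synthesis, were lower. Of 24 tested matrix genes, 15 fell, 8 rose and 1 did not pass (16 and 8 adjusted over the list alone; median −0.20, camera adjusted p = 0.0121; adjusted p = 0.404 with an estimated correlation). The matricellular gene Sparc fell from 1706 ± 46.7 to 835 ± 27.5 CPM (SD, n = 5) and the collagen cross-linking enzyme gene Loxl2, whose reads were divided between genes, by 0.69. Itgb4 fell, whereas Itga6, which encodes its laminin-binding partner, rose from 506 ± 11.6 to 842 ± 40.4 CPM. Of 28 tested lipid synthesis genes, 19 fell, 5 rose and 4 did not pass, equally adjusted over the list alone (median −0.25, camera adjusted p = 0.00363; adjusted p = 0.711 with an estimated correlation), among them Lss (−0.87), Scd1 (−0.59), Cyp51 (−0.44) and Fdft1 (−0.39). Sparc and Adamts1 of the matrix list and 8 of the 28 lipid genes, with Lss, Scd1 and Cyp51 among them, carry the 7-base word. Without carriers the calls of both lists stayed, each with an adjusted p of 0.045, and were lost with an estimated correlation (adjusted p = 0.547 for matrix and 0.676 for lipid synthesis genes).

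The other lists were not called by camera, although many of their members changed. Of 22 arterial and tip cell genes 9 rose and 9 fell, with the chemokine receptor gene Cxcr4 (1.80) and the Notch ligand gene Jag1 (0.60) up and Hey1 (−0.78), Ephb4 (−0.37) and Dll4 (−0.16) down (adjusted p = 0.539). Of 20 endothelial-to-mesenchymal transition genes 8 rose and 9 fell, with Ccn2 (0.90) and Zeb1 (0.40) up and Tgfb3 (−1.29), which has 2 copies of the 7-base word, down (adjusted p = 0.885). The TGF-beta and BMP list had 4 up and 10 down of 17 (adjusted p = 0.285), with Id2 (−1.27) and Pmepa1 (−0.97), a carrier of the word, down, and the YAP/TAZ list 5 up and 5 down of 12 (adjusted p = 0.51), with Gadd45a (1.01) up. Of 35 cell cycle genes 6 rose and 20 fell, with falls such as those of Nusap1 (−0.51), Ccnb2 (−0.37) and Plk1 (−0.30) (adjusted p = 0.0662). In the cell cycle list 5 members carry the word, Nusap1 among them. That list was called with upper-quartile factors (adjusted p = 0.0477) and without a filter on low counts (adjusted p = 0.0305). Of 26 interferon response genes 3 rose, 9 fell and 14 did not pass (adjusted p = 0.689), and Ifit2 (−0.70) and Ifi47 (−0.65) were among those that fell. Of 21 NF-kappaB and adhesion genes 12 rose and 5 fell, with E-selectin gene Sele (1.45), Ccl7 (1.52) and Ptgs2 (1.049) up (adjusted p = 0.085). Adjusted over the list alone, these lists gave equal counts except for the transition list, in which 10 fell.

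Of 17 cell junction genes 3 rose and 11 fell, among them the connexin gene Gja1 (−0.50) and Esam (−0.54) (adjusted p = 0.0934). The p53 list had 10 up and 5 down of 20 (adjusted p = 0.874), with the death receptor gene Tnfrsf10b (1.11) up and the epoxide hydrolase gene Ephx1 (−1.80) and Sesn1 (−1.12), a carrier of the 7-base word, down. Lysosome and autophagy genes had 7 up and 11 down of 23 (adjusted p = 0.19), with Npc1 (0.54) up and Gpnmb (−0.81) and Map1lc3b (−0.60), another carrier, down. The FOXO, KLF and quiescence list had 6 up and 8 down of 17 (adjusted p = 0.874), with the insulin receptor substrate gene Irs2 (1.91) up and Foxo3 (−0.56) and the cell cycle inhibitor gene Cdkn1b (−0.71), a carrier, down. Oxidative phosphorylation genes had 12 up and 8 down of 29 (adjusted p = 0.874). Within that list the cytochrome oxidase gene Cox5b, a carrier, fell from 79.0 ± 2.95 to 36.9 ± 1.54 CPM (SD, n = 5). Small ribosomal subunit genes had 2 up and 17 down of 29 (adjusted p = 0.121), such as Rps7 (−0.38) and Rps26 (−0.32). Heat shock and dissociation genes had 8 up and 1 down of 13 (adjusted p = 0.0522), with the mitochondrial chaperone gene Hspd1 up by 0.97. Adjusted over the list alone, these lists gave equal counts except for the FOXO list, in which 7 rose. The heat shock list was called in 5 of the 10 fits that left out a library, namely without control replicate 1 (adjusted p = 0.0297) or 3 (0.0408) or siRNA replicate 1 (0.0284), 4 (0.0462) or 5 (0.0331). It was also called with upper-quartile factors (0.0448) and without a filter on low counts (0.0204). Median, mean and test direction differed in sign for the arterial, transition, p53, lysosome and FOXO lists, none of which was called.

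**Figure D3:**
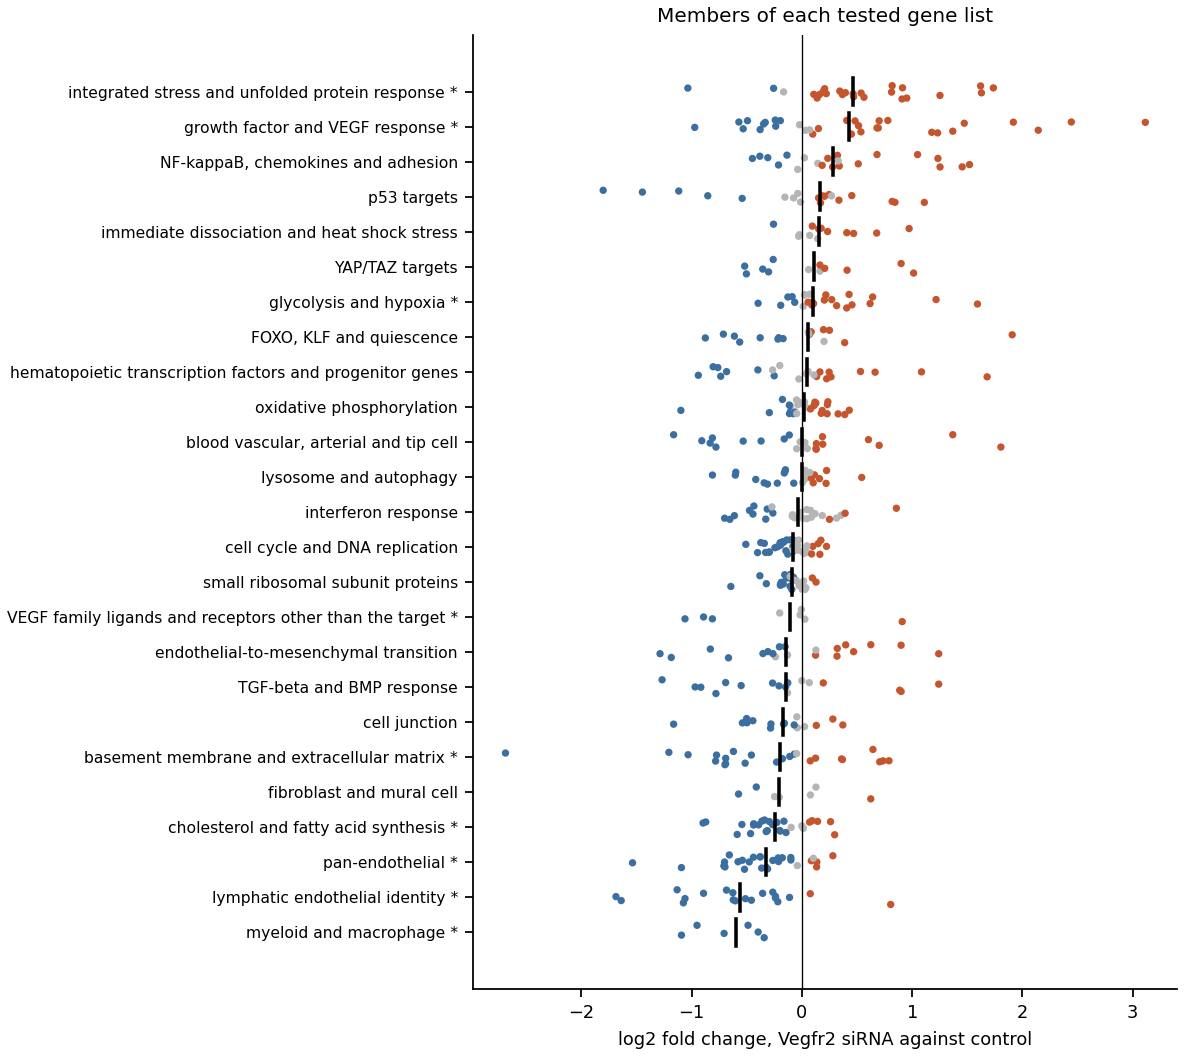
Log2 fold change (horizontal axis, Vegfr2 siRNA against control) of the members (points) of the 25 tested gene lists (rows), with the median as a black bar, members that rose in orange, that fell in blue and that did not pass in grey, and an asterisk on the 9 lists called by camera. The lymphatic list lies to the left (median −0.56) and the integrated stress list to the right (median 0.46).

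Genes with a particular 7-base word in the 3' untranslated region (UTR) were lower. The sequence of the siRNA is not given in the sources used here, so all 15915 words present in at least 100 of 11821 genes' 3' UTRs were compared. Genes with GTAAAGA (1525 genes) had a median log2 fold change of −0.13, against 0.02 for those without it. With UTR length, base composition and expression level accounted for, the difference was −0.17 (t = −13.1, Bonferroni-adjusted p = 1.25e-34), and the next lowest word, the overlapping TAAAGAA, had t = −6.92. The median was −0.12 for 1312 genes with 1 copy and −0.22 for 213 genes with 2 or more. The word was in 147 of 582 searched genes lower by over 1.5-fold (25.3%) and in 28 of 438 higher by over 1.5-fold (6.39%; two-sided Fisher's exact p = 1.67e-16). These comparisons are across genes, which are not independent replicates. The word was picked from the same fold changes, so Fisher's test restates that choice and is no separate support. In the Kdr transcript the word occurs in coding exon 11 (chromosome 5, 75961819 to 75961825) and in the 3' UTR in exon 30 (75932829 to 75932835). None of the 14 genes listed with Kdr as the largest falls carries it.

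**Figure D4:**
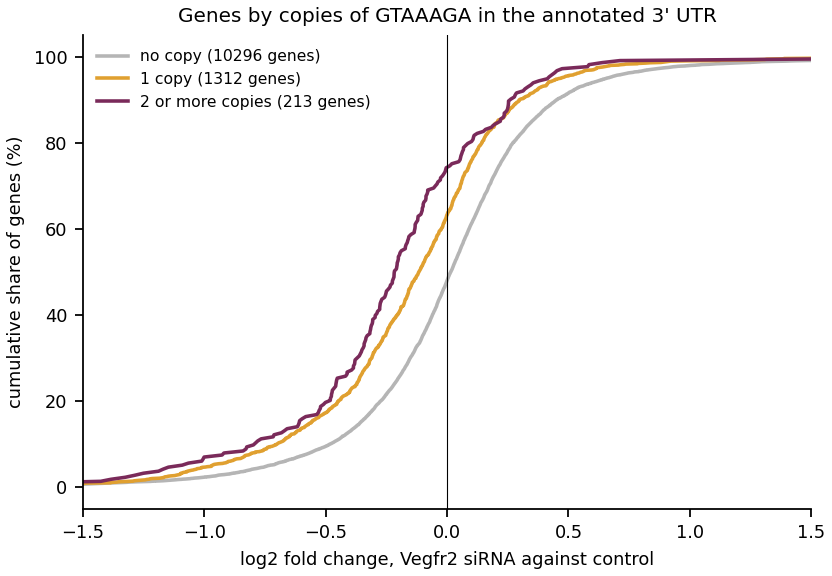
Cumulative share of genes (vertical axis, percent) by log2 fold change (horizontal axis, Vegfr2 siRNA against control, drawn from −1.5 to 1.5), for searched genes with no copy (grey), 1 copy (yellow) or 2 or more copies (purple) of GTAAAGA in the annotated 3' UTR. The curves shift to the left with the number of copies, with medians of 0.02, −0.12 and −0.22.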

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

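The tests of chance, repeat runs, GC content and seed matches were written after the counts of changed genes were seen and before the tests were run, with the edgeR dispersion, which bears on repeat runs, already known. Tests on the interferon list, on markers of other cell types and on the controls' transfection were chosen only after the results were seen, as were the confidence interval on the share of genes with 3 words and the tests without carriers of the word. In 21 of 286 sets of 5 values of a named gene (7.34%), a library lay apart from the others of its group by more than Dixon's critical value, where chance gives about 5%, and siRNA replicate 5 held 6 of them.

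In siRNA replicate 5, Sema7a (405 CPM) and Atf3 (18.1) lay above the other libraries of the group, and Itga9 (27.5), Nrp1 (6.99), Cdkn1b (75.9) and Prox1 (384) below. In siRNA replicate 1, Cd14 (69.8) was high and Vegfa (3.94), Tnfrsf10b (120.3) and Shmt2 (99.2) were low. In siRNA replicate 4, Spry4 (74 CPM) was high and Thrsp (4.94) and Slc2a1 (90.2) were low. In siRNA replicate 3, Serpina3i (2.53) was high and Stat2 (103) was low. In control replicate 2, Btnl9 (34.3) and Robo4 (239) were high and Rps7 (502) was low. Esam (49.4) was low in control replicate 1, Jag1 (66.2) high in control replicate 4 and Maf (364) high in control replicate 5. None of these 21 genes lost its call or changed sign when a library was left out.

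The number of changed genes, 8668 of 12161, is large for a knockdown. Chance is argued against: of 100 of the 126 splits of the 10 libraries into 5 and 5, only the real 1 gave as many genes. The highest of the other splits gave 0 by edgeR. At an unadjusted p under 0.05 the other splits gave 51 to 3986 genes, against 8889 in the real 1. Every other split mixes the 2 groups, which widens the spread within its sets and lowers its count. Repeat sequencing of a single library per group is argued against by the chi-square per degree of freedom, which was at least 1.498 in every pair within a group where repeat runs would give 1. Whether the 5 libraries of a group are separate cultures stays open, and a shared difference between 2 batches of cells would count as a difference between groups.

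The genes lower by over 1.5-fold may in part be direct matches of the siRNA's seed, the short stretch by which silencing complexes bind unintended transcripts, rather than responses to the loss of Kdr. As predicted before the search, the word most tied to lower fold changes among 15915, GTAAAGA, occurs in the Kdr transcript (t = −13.08, against 6.38 for the word most tied to higher ones), although 6277 of the words occur there. Bonferroni adjustment was passed by 3 words tied to lower and 6 tied to higher fold changes, so passing it does not by itself point to a seed. The third of the lower words, ATCACAC (t = −4.91), was smaller in size than that 6.38. Direct matches to the 3 leading words in annotated 3' UTRs are argued against as the whole cause, since 46.05% (95% Wilson interval 42.0% to 50.1%) of 582 lower genes carry any of them. The prediction required at least 80%, and 31.0% of genes that did not pass carry one too. Shorter matches, matches outside the 3' UTR and falls that follow from direct matches are not covered by this share, so wider seed effects stay open. GC content or transcript length is argued against as the whole cause, since 94.22% of 588 lower calls remained with those trends removed. Which falls are direct matches, which follow from those and which from the loss of Kdr stays open, because the data hold a single siRNA pattern, and Flt4, Prox1, Maf and Tie1 are among the carriers.

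The growth factor response list (19 of 32 members rose, 10 fell) and the integrated stress list (22 of 25 rose, 2 fell) were called as higher by camera. Neither was called with an estimated correlation (camera adjusted p = 0.0651 for each). An interferon response to transfected RNA of the size of that rise is argued against by the interferon list, whose median log2 fold change was −0.0394, below that of the stress list by 0.504, more than the SD of the interferon members of 0.366, although its sign depends on single libraries (from −0.0916 without siRNA replicate 5 to 0.0481 without control replicate 4) and a smaller response is not excluded. The tested fibroblast, mural and myeloid markers did not rise together, with a median of −0.396 and 1 of 13 higher. Their levels cannot decide on the number of such cells, because lymphatic endothelium also expresses some of them, such as Mrc1. The fibroblast marker Pdgfra (5 counts over control and 45 over siRNA libraries) and the epithelial marker Krt18 (1.67 and 8.22 CPM) ran the other way. Most other members of their lists under the filter did not follow them. Examples are Col1a1 (24 and 27 counts), Col1a2 (39 and 34), Dcn (22 and 11), Krt8 (4 and 0) and Krt19 (2 and 2), though Cldn7 (37 and 56) was higher. A small number of other cells is not excluded at counts this low. Transfection itself cannot be told apart from the loss of Kdr, because 0 of the control titles names a transfection without the Kdr siRNA, while control and siRNA samples share the treatment tag siRNA knockdown. A response to the loss of Kdr or to seed matches stays open as well.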

How the results depend on the processing

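Leaving out genes with the 3' UTR word and removing GC content and length trends were chosen after the data were seen. The counts of changed, higher and lower genes stayed within 1.5 times under every alternative except the 1.5-fold test, which asks for more and called 1041, 447 and 594. The lowest of the other counts were 7514 changed genes, and 3488 lower ones, without the word's carriers and Kdr, and 7753 with a mean of at least 5 CPM, both of which test fewer genes. No gene called in the main test and in another had opposite signs, but 19 main calls took the opposite sign, uncalled, with GC and length trends removed. Kdr stayed between −2.86 and −2.80 in all fits. Of 142 named genes, 79 kept direction and side in every setting that tested them, most others passing all but the 1.5-fold test. Flt1 reversed with GC and length trends removed (0.0198), called in neither. Lists called numbered 0 with an estimated correlation, 20 with fry, whose question differs, and 8 without carriers, of which the pan-endothelial and growth factor lists also passed with an estimated correlation (both adjusted p = 0.0423). For the growth factor list, which lay higher, leaving out carriers of a word picked for lower fold changes favours the call. Lists were not tested with DESeq2, limma-voom, glmTreat or GC and length trends removed. Among the settings that tested lists, the lymphatic list passed in all but 1, failing with an estimated correlation (median −0.558, adjusted p = 0.129). The hematopoietic list passed in 1 of them, fry (0.0471, adjusted p = 0.00514). The estimated correlation among the lymphatic list's genes was 0.287, against the preset of 0.01, so its call depends on that setting. For the hematopoietic list, fry asks a different question from camera. Deviations of same-numbered libraries correlated at −0.166, −0.0955, 0.0214, −0.0192 and −0.249, and no control library correlated best with its own number. The replicate numbers thus showed no sign of pairing, which does not exclude a paired design. The replicate block gave 8537 genes and called 1 more list, heat shock (adjusted p = 0.0265). Genes under the filter, such as Spi1 (1 count over control and 0 over siRNA libraries) and Vegfc (34 and 21), were not tested.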

Other observations

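Families of genes that share a symbol stem were compared only after the data were seen. Of 192 families tested, 12 were called by camera at the preset correlation and 0 with an estimated one (adjusted p at least 0.809), so they are descriptions of these libraries. All 14 genes of the proteasome stem Psmd rose (median log2 fold change 0.24), as did 17 of 20 nucleoporin (Nup) genes (0.29), 34 of 53 translation initiation factor (Eif) genes (0.15), 11 of 14 mitochondrial import (Timm) genes (0.28), and 8 of 11 Utp (0.45), 7 of 8 Rrp (0.42) and 7 of 10 Nol (0.36) genes of ribosome assembly. Of 15 tetraspanin (Tspan) genes 12 fell (−0.37), as did 7 of 8 C-type lectin (Clec) genes (−1) and 12 of 13 Pik genes (−0.34). Ddx (23 of 34 up) and Tnfrsf (7 of 13 up, 5 down) were the other called families. Ribosomal protein stems were not called (Rps 7 up and 24 down of 41, Rpl 6 up and 14 down of 48).

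Interferon response genes varied together between libraries of the same group. Their median deviation from the group mean ran from −0.18 to 0.20 log2 in control and from −0.26 to 0.22 in siRNA libraries. The SD of these medians, averaged over the 2 groups, was 0.166, above that of all 10000 random lists matched on expression, whose median was 0.0127.

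The median log2 fold change was −0.20 over 597 genes with GTAAAGA followed by A and −0.09 over 928 genes in which it was not, a difference that was not tested. Of carriers that changed, 68.4% fell, against 46.3% of other changed genes. Among oxidative phosphorylation genes, Cox5b, a carrier, had a log2 fold change of −1.10, while the other 28 tested members lay between −0.30 for Atp5c1, also a carrier, and 0.43 for Cycs, which carries the word and rose.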
